A study of Drosophila melanogaster with 2 samples.

How the data were processed

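Chromatin from whole larvae at the wandering stage of the third instar, of a woc-eGFP line, was sonicated and immunoprecipitated with an antibody against GFP, per the labels. There were 2 libraries, biological replicates 1 and 3, from separate biosamples of pooled sex and from 1 fly line; they form 1 group, so no condition was compared with another and no paired or between-group test was made. Each library's control alignment entered the authors' peak calling, per the text deposited with each library; no control library was analysed here.

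The authors deposited lists in narrowPeak format for the builds dm6 and dm3: a relaxed list per library and 1 for the pooled alignments, each holding peaks and background as input for the irreproducible discovery rate (IDR) procedure, and an optimal list after the IDR threshold. The signal of a peak is the value that the authors' caller gave it; what it measures is not stated, and the deposited lists state no scaling of signal between them, so signal was used to rank and describe peaks within a list, and ratios between the libraries' signals describe these lists only. The −log10 q of each peak is also the authors' value, and reached a ceiling in every list (3.94 in the pooled list on dm6, shared by 4385 peaks). The caller, the aligner, the IDR threshold and their versions are not given in the sources used here. The score column held 0 throughout. Relaxed lists held 29999 peaks on dm6 and 30000 on dm3 whatever the library, so their length says nothing about a library. All 6636 optimal peaks on dm6 were found in the pooled list, and they were exactly the pooled peaks at or above the lowest optimal signal of 99.6. Some peaks share an interval and differ in their summit: the optimal list had 6451 distinct intervals. Read totals were not used here, so depth is unknown, and binomial intervals cover counting error over peaks or genes only.

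Peaks were compared with the Ensembl release 115 annotation (BDGP 6.54) and the matching dm6 sequence, on 2L, 2R, 3L, 3R, 4 and X. Coordinates are 1-based and on dm6; none were converted between builds, and dm3 lists were compared by count and signal only. A gene was called bound where an optimal summit lay within 500 bp of any TSS of a protein-coding transcript, and its value is the signal of the highest such peak. Summits elsewhere were placed, in this order, in 5' untranslated regions, coding exons, 3' untranslated regions, introns or intergenic sequence. A gene's value in each library is the highest-signal peak of that library overlapping the optimal peak by 1 bp or more.

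The tests in this paragraph were fixed before the data were examined; tests added later are marked so where they stand. The promoter share, the overlap of the libraries and the counts near arm ends were set against 1000 circular shifts, which move all peaks of an arm by 1 random offset (annotation categories and the interval alternative used 100). Gene lists, arms, motifs and divergent promoters were tested with two-sided Fisher's exact tests with 95% exact conditional intervals, and p-values of 27 lists, 16 motifs and 2 arms were adjusted by Benjamini and Hochberg's method within each family, with a threshold of 0.05. These tests run over genes or peaks of 1 pooled list. Neighbouring genes are not independent, and the p-values do not measure the spread between animals. The gene lists and motifs were also fixed beforehand; 10 older gene symbols were matched through synonyms and all list members were found. Motifs were searched on both strands from 150 bp upstream to 50 bp downstream of the TSS nearest the summit of a bound gene, or of the 5'-most TSS of an unbound gene. A divergent gene has a TSS within 1000 bp of that of an opposite-strand gene pointing away.

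Genes were named by a rule fixed beforehand: woc, row, HP1c and HP1b; all members of the ecdysteroid biosynthesis and telomere capping lists; the 15 genes with the highest promoter signal; from every other list the 3 highest bound members and the alphabetically first unbound one; and the 5 highest peaks with no TSS within 500 bp. The lists were ecdysteroid biosynthesis, ecdysone response, telomere capping, the HP1c, woc and row complex, insulator and architectural proteins, cytoplasmic and mitochondrial ribosomal proteins, proteasome, tRNA synthetases, oxidative phosphorylation, replication, spliceosome, histones, heat shock, Hox, chemoreceptors, cuticle, salivary glue and late puff, chorion with vitelline and yolk, testis, Jonah proteases, antimicrobial peptides, and markers of muscle, fat body, neurons, hemocytes and gut.

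Alternatives changed 1 choice at a time, but for summits against flanks, which changed the sites, the span and the control sequence of the motif test together. They were the window around the TSS (250 and 1000 bp), the 3318 optimal peaks of highest signal, the 6636 highest peaks of 1 library in place of the optimal list, overlap of intervals in place of summits, genes with no other TSS within 1000 bp, other motif spans and controls, other overlap rules and the dm3 build. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The list test was tested on 20 simulated peak sets over 13945 genes, with 60% of a planted list of 50 genes and 20% of other genes given a peak: the planted list was called in 20 of 20 sets, and 2 of 520 random lists of 30 genes were called. Simulated lists were drawn at random from all genes, and each gene was given its peak independently. These rates therefore do not cover lists of clustered or divergent genes, nor smaller lists. The shift test of the promoter share called 20 of 20 simulated sets with a promoter preference and 1 of 20 without one.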

Results

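ChIP-seq of the zinc finger protein woc (without children) was recorded in whole Drosophila melanogaster larvae at the wandering stage of the third instar, shortly before pupariation. The flies carried a transgene for woc fused to eGFP, and DNA bound by the fusion was recovered from sonicated chromatin with an antibody against GFP. The 2 libraries, biological replicates 1 and 3, came from separate samples of pooled males and females and formed 1 group, with no second condition. The measurements were peak positions on the genome build dm6 (and separately on dm3), each with a signal and a −log10 q from the authors' peak caller. Read counts were not used here, so the depth of each library is unknown.

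The authors' optimal list, the pooled peaks left after their IDR threshold, held 6636 peaks on dm6. These were exactly the pooled peaks at or above a signal of 99.6, and the list does not state that each was found in both libraries. Of these, 6614 lay on the chromosome arms 2L, 2R, 3L, 3R, 4 and X, and 22 lay on the mitochondrial sequence. Merging overlapping peaks left 5616 regions that covered 2.57 Mb. Signal in the list ran from 99.6 to a highest value on the arms of 2866, with a median of 184. The strongest peak on the arms was at 2L:480572-481411, with its summit at 481101, in an intron of ush, a cofactor of GATA transcription factors, and 1413 bp from the nearest transcription start site (TSS), that of cbt. The next peaks lay at promoters. A signal of 2238 was recorded at a TSS of larp, a La-related RNA-binding protein (summit 3R:28326608, 344 bp from the TSS), and 1952 at Ugalt, a UDP-galactose transporter (summit X:2703895, 43 bp from the TSS). The promoter of CG18549 had a signal of 1864 (summit 3R:12449171), and that of Sox14, a transcription factor gene induced by ecdysone, 1803 (summit 2R:23978534). A single peak of signal 1786 between CenG1A and mRpS23, with its summit at 2L:13835458, lay 106 bp from the CenG1A TSS and 386 bp from the mRpS23 TSS. CG9147 and Fbw5 likewise shared a peak (signal 1654, summit 2L:6066084), as did CG7601 and CIA30, an assembly factor of respiratory complex I (signal 1439, summit 3R:29736851).

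The remaining genes among the 15 with the highest promoter signal were ph-p, a Polycomb group gene (1637), the small heat shock gene Hsp27 (1447), CG14100 (1433), and the pair Chro and Ssl1 (1393). Chro encodes the chromodomain protein Chromator and Ssl1 a subunit of the transcription factor TFIIH, and their shared summit at 3L:22878875 lay 107 bp from the Chro TSS. A further 4 of the strongest peaks lay away from promoters. They fell in introns of CG11050 (signal 1798, summit 2L:6612703), of the kinase gene Lk6 (1636, summit 3R:11761052) and of Zw, the glucose-6-phosphate dehydrogenase gene (1471, summit X:19668590), and in an intergenic stretch 3732 bp from the TSS of CG31668 (1525, summit 2L:2202434). Each of these 5 peaks away from promoters, the ush peak included, was also present in both libraries' own lists. This was close to fixed beforehand, because the peaks were picked by the pooled signal of these same libraries. At ush the signal was 758 in the replicate 1 library and 2150 in the replicate 3 library.

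The comparison of replicate 1 with replicate 3 was the only one between samples that the labels allowed. Both libraries recorded the leading promoters: larp had a signal of 570 and rank 3 in replicate 1, and 1673 and rank 2 in replicate 3, while Sox14 ranked 5 in each. Ranks of other leading promoters lay further apart, with Ugalt at 31 in replicate 1 and 3 in replicate 3, and ph-p at 67 and 6. The leading promoters were picked by the pooled signal of these same libraries. Of the 6614 optimal summits on the arms, 96.3% lay inside a peak of the replicate 1 library's own relaxed list (exact 95% interval 95.8% to 96.7%) and 98.7% inside one of the replicate 3 library (98.4% to 98.9%). These shares are close to fixed by how the lists were made, and no shifted value was computed for them. The optimal peaks come from the pooled alignments of both libraries, and each relaxed list holds 29999 peaks and background. When each library's list was limited to its 6636 highest-signal peaks, 78.1% of the replicate 1 peaks on the arms overlapped a replicate 3 peak (77.1% to 79.1%) and 74.9% of the replicate 3 peaks overlapped a replicate 1 peak (73.9% to 76.0%). Circular shifts of the peaks along each arm gave means of 3.86% and 3.75%, and neither share was reached in 1000 shifts (one-sided permutation p = 0.001 each, the smallest that 1000 shifts can give). Requiring summits within 100 bp lowered the first share to 60.6%.

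Across the 6282 optimal summits found in both full lists, Spearman's rho between the libraries' signals was 0.620 and Pearson's r of log10 signal was 0.641. These values are across peaks, which are not independent replicates, and were not tested. The replicate 3 signal was higher, with a median ratio to replicate 1 of 2.06. This ratio was 1.70 at the 2754 summits at promoters (interquartile range 1.25 to 2.32) and 2.45 at the 3528 summits away from them (1.77 to 3.25). Of the optimal summits, 70.9% lay in both libraries' top lists, 8.94% in that of replicate 1 alone and 19.2% in that of replicate 3 alone. Promoters held 48.0% of the summits supported by both top lists, 56.9% of the 591 supported by replicate 1 alone and 24.4% of the 1268 supported by replicate 3 alone. These shares, split by library after the data were seen, rest on 1 library each; a test over peaks would not measure the spread between libraries, so no p is given for their difference.

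**Figure D1:**
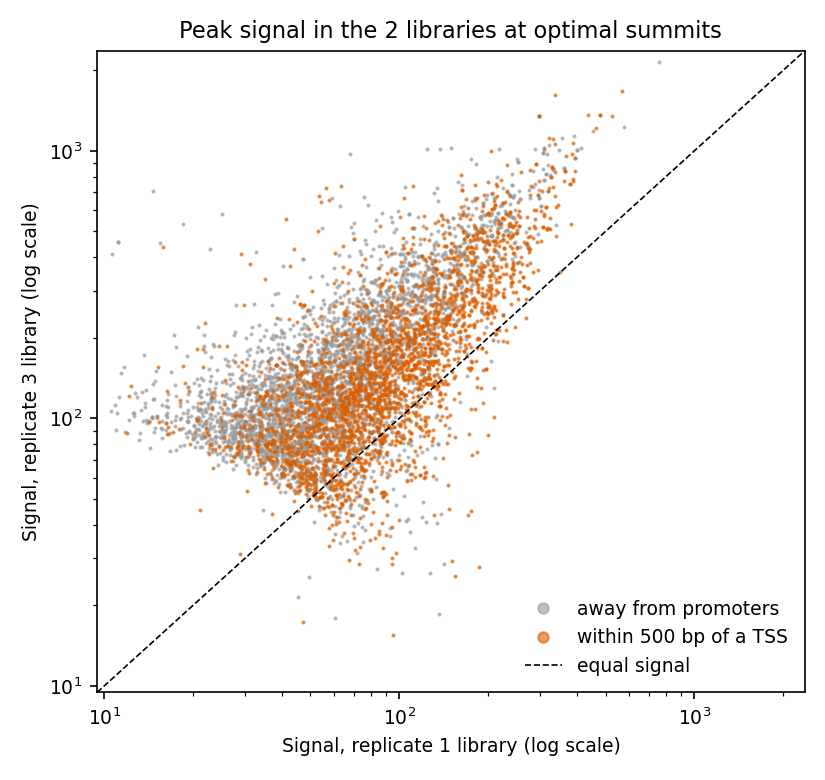
Signal of the overlapping peak in the replicate 1 library (x axis, log scale) and the replicate 3 library (y axis, log scale) at the 6282 optimal summits found in both full lists; orange points lie within 500 bp of a TSS, grey points do not, and the dashed line marks equal signal. Most points lie above the line, with a median ratio of 1.70 at promoters and 2.45 away from them.

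Promoters of protein-coding genes held a large part of the woc-eGFP peaks. Of the 6614 summits, 2923 (44.2%, exact 95% interval 43.0% to 45.4%) lay within 500 bp of an annotated TSS, against a mean of 11.4% for 1000 circular shifts, a 3.87-fold difference (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). In all, 3058 of 13945 protein-coding genes on the arms (21.9%) had a summit at a promoter, and these genes are called bound below. The share at promoters was 56.6% among the 10% of peaks with the highest signal (52.8% to 60.5%), 32.5% in the ninth of 10 such bins (29.0% to 36.2%) and 39.9% in the last. At the 625 bound genes that had a single TSS and no divergent partner, the summit lay upstream of the TSS in 91.8% (89.4% to 93.9%), with a median position of -112 bp.

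Away from promoters, 2371 summits (35.8%) lay in introns, 1228 (18.6%) were intergenic, 44 (0.665%) lay in 3' untranslated regions and 42 (0.635%) in 5' untranslated regions. Coding exons held 6 summits (0.0907%), against 13.9% of shifted summits. Introns held 39.4% and intergenic sequence 30.01% of shifted summits. In the single libraries the promoter share of the 6636 highest-signal peaks was 49.6% for replicate 1 and 42.3% for replicate 3.

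**Figure D2:**
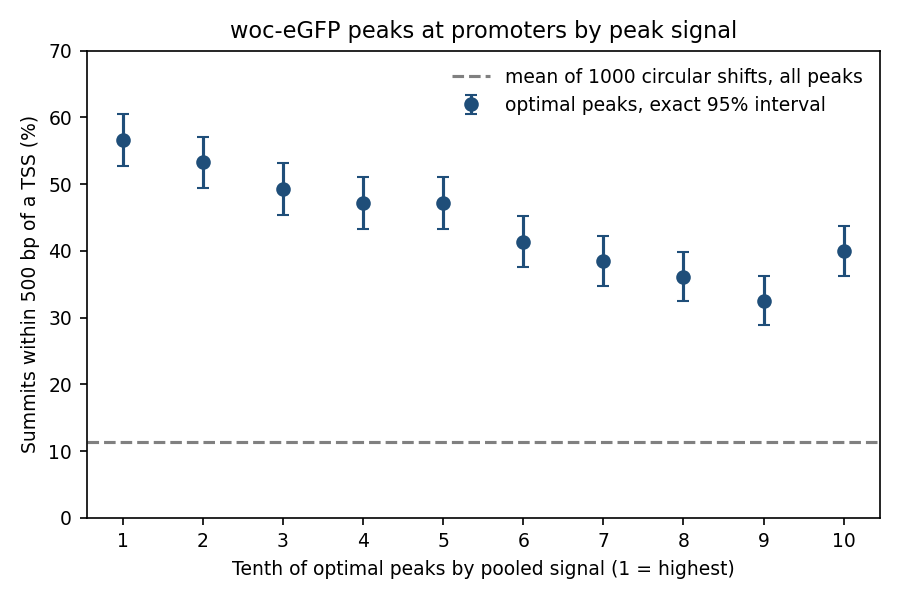
Percentage of optimal summits within 500 bp of a protein-coding TSS (y axis) in 10 equal bins of the optimal peaks ordered by pooled signal (x axis, 1 is the highest); points show the share and bars the exact 95% binomial interval, which covers counting error only. The share is 56.6% in the first bin and 32.5% in the ninth, all above the mean of the circular shifts at 11.4% (dashed line).

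Genes tied to woc itself were examined first. Neither the woc promoter nor that of HP1c, a heterochromatin protein 1 family member, was bound: the nearest optimal summits lay 17184 bp from a woc TSS and 18824 bp from an HP1c TSS. The promoter of row (relative of woc), which encodes a related zinc finger protein, had a signal of 546 with the summit at 2R:15213693, 59 bp from the TSS, and HP1b had 206 with the summit at X:9081156. In the list of 7 genes for the complex of HP1c, woc and row and its partners, 5 were bound (71.4%), against 21.9% of other genes (odds ratio 8.91, 95% interval 1.46 to 93.6, two-sided Fisher's exact test, adjusted p = 0.0264). Chro (1393) and pzg (266) were among them. Too few members had no other gene's TSS within 1000 bp for the list to be tested on such genes. With the 6636 highest peaks of replicate 3 alone the odds ratio was 4.78 and with those of replicate 1 alone 4.31, and the call was lost in both (adjusted exact p = 0.101 and 0.132), as it was within 250 bp (57.1%, adjusted exact p = 0.0789).

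Among 13 genes of ecdysteroid biosynthesis, the pathway that makes the moulting hormone, 2 were bound (15.4%, adjusted exact p = 0.775). These were Npc1a, a sterol trafficking gene, with a signal of 442 at a summit (2L:10221165) that it shared with the proteasome gene Prosalpha6, and sro, with 109 at 3R:29794302. The other 11, nvd, spo, spok, phtm, dib, sad, shd, Start1, mld, ouib and ecd, had no optimal summit within 500 bp, and only mld (50.9) and shd (60.8) had a relaxed pooled peak there. The chromatin came from whole larvae, so binding confined to a small tissue could be missed. An unbound call therefore does not show that woc-eGFP was absent from a gene in every tissue, whatever the gene list. Of 21 genes of the ecdysone response, 9 were bound (42.9%, odds ratio 2.68, 95% interval 0.994 to 6.92), with an adjusted exact p of 0.0770. The highest were the nuclear receptor gene Eip75B (1004), ImpE3 (512) and usp (357), the partner of the ecdysone receptor, while br was unbound, with a relaxed pooled peak of 94.6. The list did pass with the highest peaks of replicate 3 alone (47.6%, adjusted exact p = 0.0454) and of replicate 1 alone (61.9%, adjusted exact p = 0.000774), with the 3318 optimal peaks of highest signal (38.1%, 0.0232) and with overlap of peak intervals in place of summits (47.6%, 0.0411).

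Of 14 telomere capping genes, 6 were bound (42.9%, odds ratio 2.67, 95% interval 0.764 to 8.79, adjusted exact p = 0.174). They were ver (signal 525), cav, which encodes the capping protein HOAP (306), the gene for HP1a (287), tefu, the fly ATM kinase gene (282), peo (242) and eff (165). The tefu summit at 3R:15242546 was also 141 bp from the TSS of Hsc70-4. The unbound members were HipHop, moi, tea, mre11, rad50, nbs, mei-41 and mus304.

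Genes for proteins of insulators and chromosome architecture were bound more often than other genes. Of 15, 11 were bound (73.3% against 21.9%, odds ratio 9.82, 95% interval 2.91 to 42.3, Fisher's exact adjusted p = 0.00014), led by Chro (1393), Cp190 (802) and BEAF-32 (358), while CTCF was unbound. Chro and pzg stood in this list and in that of the HP1c, woc and row complex. Cytoplasmic ribosomal protein genes were bound in 50 of 86 cases (58.1%, odds ratio 5.01, 95% interval 3.19 to 7.93, adjusted exact p = 4.46e-12), with signals of 569 at RpL32, 471 at RpS3A and 459 at RpS20, and none at RpL10Aa. Mitochondrial ribosomal protein genes were bound in 35 of 73 cases (47.9%, odds ratio 3.31, 95% interval 2.02 to 5.38, adjusted exact p = 5.71e-06), with 1786 at mRpS23, 1336 at mRpS10 and 900 at mRpL41, while mRpL1 was unbound. Among genes with no other gene's TSS within 1000 bp, the cytoplasmic ribosomal proteins kept 51.6% bound (adjusted exact p = 6.98e-06), against 13.6% of other such genes. The mitochondrial ones had 15.4% (2 of 13; odds ratio 1.14, 95% interval 0.123 to 5.23, adjusted exact p = 0.881). The insulator list was left with 4 such genes, 2 of them bound (odds ratio 6.28, 95% interval 0.455 to 86.7, adjusted exact p = 0.274), too few to show whether its excess held.

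Other groups that most dividing or growing cells use did not differ from the remaining genes past the threshold. The shares were 26.3% of 80 oxidative phosphorylation genes (ND-ASHI 601, ND-MWFE 561, ND-24 471, ATPsynB unbound), 28.6% of 35 tRNA synthetase genes (AspRS 440, GluProRS 431, ArgRS 354, AlaRS-m unbound) and 18.8% of 48 proteasome genes (Rpn5 822, Prosalpha6 442, Rpn11 347, Prosalpha1 unbound). They were 32.1% of 28 spliceosome genes (Sf3b6 442, noi 222, Sf3b3 204, Prp18 unbound) and 25% of 28 replication genes (Mcm2 354, dup 277, geminin 256, Cdc45 unbound). The adjusted exact p of these 5 lists ran from 0.354 to 0.775. Of 16 heat shock genes 7 were bound (43.8%, adjusted exact p = 0.127), led by Hsp27 (1447), Hsp26 (528) and Hsc70-4 (282), with Hsc70-3 unbound. This list passed as higher within 1000 bp (68.8%, adjusted exact p = 0.00111) and with overlap of peak intervals (56.3%, 0.0159).

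Chemoreceptor and cuticle protein genes were bound less often than other genes in this whole-larva chromatin. Of 179 chemoreceptor genes 2 were bound, Gr97a (263) and Ir31a (108), a share of 1.12% (odds ratio 0.0396, 95% interval 0.00476 to 0.145, adjusted exact p = 2.80e-15), and Gr10a was among the unbound. Of 118 cuticle protein genes 1 was bound, Cpr72Eb (250), a share of 0.847% (odds ratio 0.0301, 95% interval 0.000756 to 0.171, adjusted exact p = 7.06e-11), with Ccp84Aa unbound. None of 111 replication-dependent histone genes was bound (adjusted exact p = 1.42e-11), His1:CG31617 among them. These genes form 1 cluster of near-identical repeats on 2L, where reads cannot be placed on 1 copy and where the relaxed pooled list held 0 peaks, so neither the count nor its p shows that they lack woc-eGFP. In the testis-specific list 1 of 31 was bound, Mst85C (196), with dj unbound (3.23%, adjusted exact p = 0.0264). That call was lost under 4 alternatives: within 250 bp (adjusted exact p = 0.0966), with the 3318 peaks of highest signal (0.241), with the top peaks of replicate 1 alone (0.0531) and among genes with no other TSS within 1000 bp (0.274).

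No member was bound in the lists for salivary glue and late puff genes (18 genes, Eig71Ea among them, adjusted exact p = 0.0588), Jonah proteases (16, Jon25Bi, 0.0770), antimicrobial peptides (14, AttA, 0.113), gut markers (12, alphaTry, 0.156) and hemocyte markers (11, Col4a1, 0.231). Under some alternatives 2 of these lists passed as lower, still with no member bound: salivary glue and late puff genes within 1000 bp (adjusted exact p = 0.0331), with the top peaks of replicate 1 alone (0.0380) and with overlap of peak intervals (0.0308), and Jonah proteases within 1000 bp (0.0428). The chorion, vitelline and yolk list had 1 of 18 bound (adjusted exact p = 0.236), and this was Cp190, an insulator protein gene whose name the list's pattern took in; Cp15 was unbound. Muscle markers had 1 of 15 bound (Tm1, 129; Act57B unbound; adjusted exact p = 0.324), fat body markers 1 of 10 (apolpp, 300.1; Fbp1 unbound; 0.775), neuron markers 3 of 13 (elav 613, futsch 344, Syx1A 106; brp unbound; 1) and Hox genes 2 of 8 (Antp 127, Dfd 106; abd-A unbound; 0.775). The threshold over the 27 lists was an adjusted p of 0.05.

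**Figure D3:**
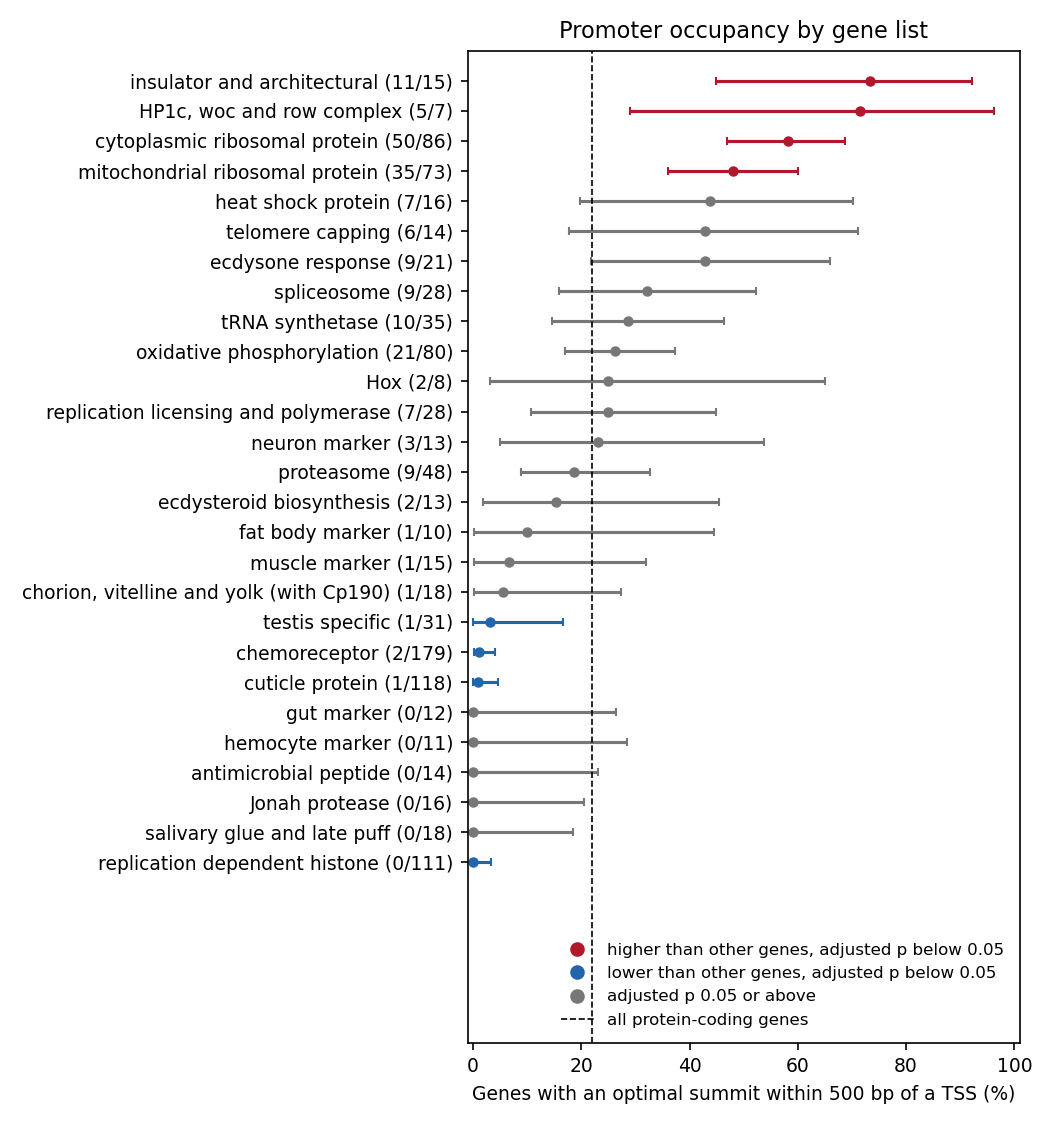
Percentage of each gene list's members with an optimal summit within 500 bp of a TSS (x axis), with bound and total members in the row labels; points show the share, bars the exact 95% binomial interval, colours the call of Fisher's exact test, and the dashed line all 13945 protein-coding genes (21.9%). The 4 lists in red had between 47.9% and 73.3% bound, and the 4 in blue between 0 and 3.23%, the histone repeats among them.

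Genes with a divergent partner were bound more often than other genes. Of 5052 genes whose TSS lay within 1000 bp of the TSS of a gene on the opposite strand pointing away, 1834 were bound (36.3%), against 1224 of 8893 others (13.8%; odds ratio 3.57, 95% interval 3.28 to 3.88, two-sided Fisher's exact p = 5.15e-203). A gene of such a pair has a second TSS in reach of a summit: if each gene had its own peak at the 13.8% of genes with no other TSS within 1000 bp, and every peak counted for all linked genes, 27.3% of divergent genes would be bound. The same reckoning gives 15.2% of the other genes, and so an odds ratio of 2.10 from reach alone; it was added after the data were seen and carries no test. Counting 1 gene of each group of linked genes, so that no pair entered more than once, gave an odds ratio of 3.55 (95% interval 3.19 to 3.94, also added later), which does not remove the partner's peak. The pairs CenG1A and mRpS23, CG9147 and Fbw5, CG7601 and CIA30, and Chro and Ssl1 were among them. Of the bound genes, 50.98% shared their peak with another bound gene, so a peak could not be given to 1 gene of such a pair. Divergent genes made up 79.5% of the mitochondrial ribosomal protein list and 61.6% of the cytoplasmic one, against 36.2% of all genes. Within the divergent genes, 56.9% of the mitochondrial ribosomal protein genes were bound and 36.1% of other genes; among the rest the shares were 13.3% (2 of 15) and 13.8%.

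The small chromosome 4 stood apart from the other arms. Of its 80 protein-coding genes 45 were bound (56.3%), RpS3A (471) and apolpp (300.1) among them, against 21.7% elsewhere (odds ratio 4.63, 95% interval 2.91 to 7.43, two-sided Fisher's exact test, adjusted p = 4.81e-11). Peak density on chromosome 4, at 48.2 summits per Mb, was within the range of the large arms, from 45.6 on 2R to 54.1 on X. On X, 24.2% of 2196 genes were bound against 21.5% elsewhere (odds ratio 1.16, 95% interval 1.04 to 1.30, adjusted exact p = 0.0059), a call that was lost with summits within 250 bp (odds ratio 1.08, adjusted exact p = 0.227) and with the 3318 optimal peaks of highest signal (1.05, 0.444). On 2L, 2R, 3L and 3R the shares were 20.7%, 19.6%, 22.5% and 22.2%.

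The ends of the assembled arms held few peaks. Within 50 kb of the 12 ends lay 3 summits, against a mean of 29.96 in 1000 circular shifts (one-sided permutation p for more peaks than shifted = 1); 1 of the 1000 shifts gave 3 or fewer, a lower tail looked at after the count was seen. Each of the 3 peaks lay at a promoter: at krz (signal 103, summit 3R:32051989) and Map205 (119, summit 3R:32068462, 10869 bp from the end), both at the telomeric end of 3R, and at PlexB (356, summit 4:43832) near the centromeric end of 4. The genes were named because the count was small, after their values were seen. Of the 12 ends, 6 were telomeric and held 2 of the summits, and 6 were pericentromeric and held 1. No dm6 list had a summit within 50 kb of the pericentromeric ends of 2L, 2R, 3L, 3R and X. The same was true of the telomeric ends of 4 and X. No shifted value was computed for telomeric ends alone, so the low count is not a result about telomeres. Arm ends hold repeated sequence, and the telomeric repeats beyond the assembly were not measured.

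Promoters of bound genes held several core promoter elements more often than promoters of unbound genes. From 150 bp upstream to 50 bp downstream of the TSS, the Ohler motif 7 was present at 19.98% of 3058 bound and 8.40% of 10887 unbound promoters (odds ratio 2.72, 95% interval 2.43 to 3.05, Fisher's exact adjusted p = 7.66e-64). The DNA replication-related element (TATCGATA), the binding site of DREF, stood at 11.2% against 7.12% (odds ratio 1.64, 1.43 to 1.88, adjusted exact p = 7.46e-12). The GAGA motif had an odds ratio of 1.68, the Ohler motif 6 of 1.49, the E-box (Ohler motif 5) of 1.46, the core of Ohler motif 1 of 1.46, its longer form bound by M1BP of 1.35, and the BEAF-32 element CGATAT of 1.34. The TATA box was present at 3.89% of bound and 9.30% of unbound promoters (odds ratio 0.395, 0.322 to 0.480, adjusted exact p = 1.88e-24) and the initiator at 22.3% and 31.2% (odds ratio 0.631, 0.574 to 0.694, adjusted exact p = 7.10e-22).

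The TCT motif, the CA repeat, the A tract, the su(Hw) site, the CTCF core and the ecdysone response element did not differ past the threshold (adjusted exact p from 0.0764 to 1 over the 16 motifs tested). Over the longer span from 500 bp upstream to 100 bp downstream the TCT motif (odds ratio 1.11, adjusted exact p = 0.0117), the CA repeat (1.23, 0.00583) and the A tract (1.18, 0.000251) passed as higher and the CTCF core (0, 0.0386) as lower. With summits within 1000 bp the TCT motif (1.19, adjusted exact p = 0.0013) and the CA repeat (1.37, 0.00526) passed as higher. The TCT motif also passed with the top peaks of replicate 3 alone (1.13, 0.0497), and the A tract with those of replicate 1 alone (1.15, 0.0463). A comparison of the sequence within 100 bp of all summits with flanks 500 bp away, which differs in sites, span and control sequence, gave other directions for several motifs: the TATA box was then more frequent at summits (odds ratio 1.81, 95% interval 1.54 to 2.13), and the GAGA motif (0.934) and E-box (0.905) no longer stood higher. The replication-related element (6.89) and Ohler motif 7 (2.51) were higher at summits in this comparison too. Summits and flanks also differed in base composition, on which they were not matched. Mean GC was 36.8% at summits at promoters against 44.6% at 500 bp on either side. Away from promoters it was 36.2% against 43.8% and 43.0%. Against flanks the su(Hw) site (2.59, adjusted exact p = 0.00543) and the A tract (1.35, 1.46e-11) also passed as higher, and the CA repeat (0.604, 9.28e-14) as lower. With the 3318 optimal peaks of highest signal 4 motifs lost their call: the BEAF-32 element (odds ratio 1.102, adjusted exact p = 0.238), the core of Ohler motif 1 (1.20, 0.112), its longer form (1.20, 0.151) and Ohler motif 6 (0.912, 0.866), which also lost it with the top peaks of replicate 3 alone (1.35, 0.0602).

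**Figure D4:**
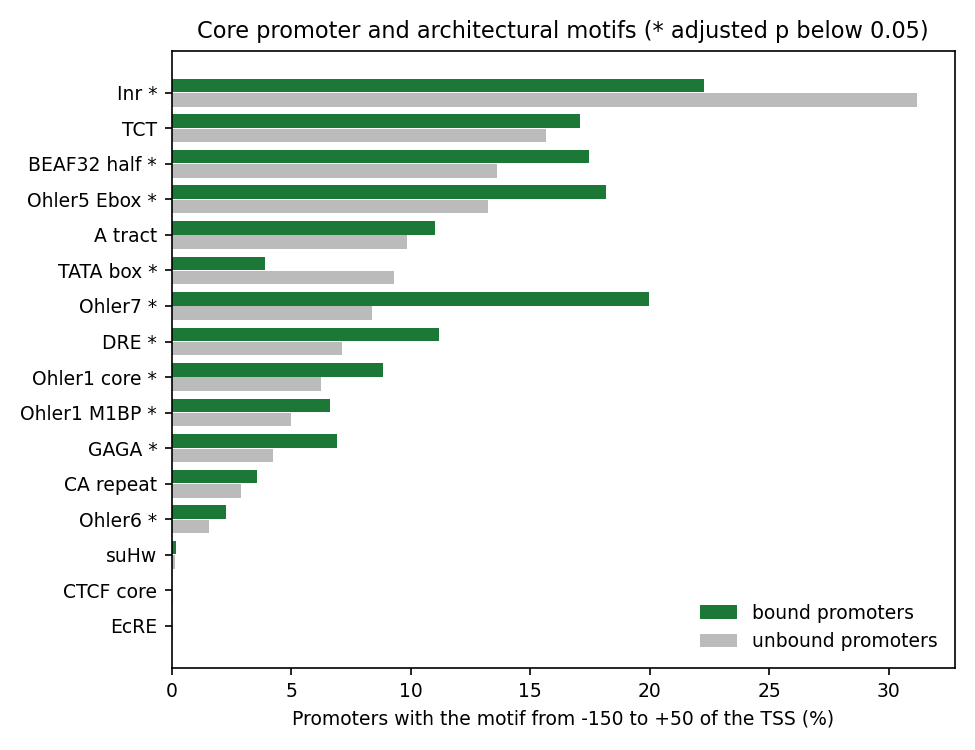
Percentage of promoters with each motif from 150 bp upstream to 50 bp downstream of the TSS (x axis) for 3058 bound genes (green) and 10887 unbound genes (grey); an asterisk marks an adjusted p below 0.05 in Fisher's exact test. Ohler motif 7 stands at 19.98% and 8.40%, and the TATA box at 3.89% and 9.30%.

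The same libraries processed against the older build dm3 gave 6773 optimal peaks, so the dm6 count was 0.980 times that of dm3. Signal on the arms reached 2867 on dm3 and 2866 on dm6, and the medians were 180.0 and 184. The lists differed at the mitochondrial sequence, with 3 optimal peaks on dm3 (highest signal 266) and 22 on dm6 (highest signal 8487.5). On dm3 a further 18 optimal peaks lay on sequence outside the arms and the mitochondrial genome. Peaks with a −log10 q of 2 or more numbered 4893 in the replicate 1 and 8874 in the replicate 3 library on dm6, and 5073 and 8784 on dm3. Overlap of the libraries' top lists on dm3 was 77.9%.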

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

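The tests of the mitochondrial peaks and of the threshold's part in the coding exon count were chosen after those results were seen; the tests of base composition and of shared promoters were written down beforehand.

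The optimal dm6 list held 22 peaks on the mitochondrial sequence, outside every comparison on the arms, with no control library to set them against, and the highest had a signal of 8487.5, 2.96 times that of the strongest peak on the arms. The peaks covered 62.3% of the 19524 bp mitochondrial sequence, and those of the single libraries 72.7% in replicate 1 and 48.98% in replicate 3. Relative to its highest signal on the arms, the highest mitochondrial signal was 9.997 in the replicate 1 library and 0.483 in the replicate 3 library, a ratio of 20.7. Mitochondrial DNA carried over in unequal amounts may account for both values, but this cannot be told apart from other sources: the criteria were set after the values were seen, and the replicate 3 peaks covered less than the 50% that was asked for. The count on dm3 was 3 peaks; whether dm3 sequence outside the mitochondrial genome resembles it and takes up its reads cannot be told apart from other differences between the builds, because the dm3 sequence was not used here, and no biological explanation was tested.

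Coding exons held 6 of the 3691 optimal summits away from promoters (0.163%, exact 95% interval 0.0597% to 0.353%), against a mean of 15.9% for shifted summits. The bound sequence was low in GC, with a mean of 37.3% within 100 bp of these summits against 51.9% at random positions in coding exons. Base composition could therefore lower the count, yet random positions matched on GC lay in coding exons in 6.87% of cases (range over 100 draws 5.96% to 8.02%), above the summits' interval, so it is not the whole cause. The authors' threshold is not the whole cause either: among 19045 pooled peaks below it and away from promoters 1.28% had the summit in a coding exon (1.12% to 1.45%). Other sources of the difference stay open, and no biological explanation was tested.

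Mitochondrial ribosomal protein promoters were bound more often than others (47.9%), and 79.5% of these genes have a divergent partner, so the peak may belong to the partner. The prediction was that, if having a partner were the whole cause, the list would match other genes once divergent and remaining genes are compared separately. The Mantel-Haenszel odds ratio within these strata was 2.11 (95% interval 1.30 to 3.42), below the unstratified 3.31 but above 1. So the larger share of genes with a partner was not the whole difference. The test cannot show whose peak it is: partners bound more often than other partners would leave the same excess in divergent members. The excess was seen in the 58 divergent members (56.9% against 36.1%), while the 15 others had 13.3% against 13.8%, too few to show a difference. Which gene of a pair a peak belongs to stays open.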

How the results depend on the processing

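Of 416 values recomputed under an alternative, 346 kept their direction and side of the threshold or, where they had no test, stayed within 1.5 times the main count or within the 95% interval of the main share; lists called lower thus went from 4 to 6 and motifs called higher from 8 to 11 within the tolerance for counts. In a further 20, of lists and motifs without a call, the odds ratio lay on the other side of 1 and still had no call. The promoter share, the divergent promoter odds ratio and the chromosome 4 odds ratio kept their calls under every alternative run for them. The count near arm ends, tested for more peaks than shifted, had no call in the main setting or under any alternative. Read depth was unknown, so its effect could not be examined; a stricter IDR score was not run, because the score column held only 0. The following alternatives were chosen after seeing the data: the 5'-most TSS for bound genes, the chorion list without Cp190 and 1 gene of each group of linked genes, none of which changed a call, and the ratios of dm6 to dm3 peaks with a −log10 q of 2 or more, at 0.965 and 1.01 in the single libraries.

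The overlap of the libraries' top lists, 78.1%, was 60.6% with summits within 100 bp, 54.2% with a reciprocal overlap of 50% and 72.5% for the top 1000 peaks. Bound genes numbered 1985 with the 3318 peaks of highest signal, a set that holds fewer peaks by construction. Among genes with no other TSS within 1000 bp, 1 list was higher and 2 were lower, in place of 4 and 4. Too few such genes were left to test 3 lists: telomere capping, salivary glue and late puff, and the HP1c, woc and row complex. The last was 1 of the 4 higher lists, so its call was not checked in this way. The X odds ratio was 1.08 within 250 bp and 1.05 with those 3318 peaks, with the call lost. With them 4 motifs were higher in place of 8, and Ohler motif 6 turned to 0.912. Against flanks 1 motif was lower in place of 2, and the odds ratios of the E-box (0.905), TATA box (1.81), initiator (1.01), GAGA motif (0.934) and CA repeat (0.604) lay on the other side of 1. The comparison with flanks also changed the sites and the span, so these values belong to no single choice. The cause of the changes was not tested.

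Of 213 values for single lists 10 lost and 10 gained a call, and of 128 for single motifs 8 lost and 11 gained one, while the TATA box kept a call in the other direction.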

Other observations

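All tests in this part were chosen after seeing the data; the 2 tests of 8-base words on held-out arms followed a look at the words on all arms, so the held-out arms were not unseen.

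Peaks of woc-eGFP were also present at noncoding genes. Of 3261 long noncoding and other ncRNA genes, 284 (8.71%) had an optimal summit within 500 bp of a TSS, against a mean of 142 under 1000 circular shifts (permutation p = 0.001, the smallest that 1000 shifts can give; adjusted permutation p = 0.00599 over 6 classes). Among those over 1 kb from any protein-coding TSS the share was 6.16% (143 of 2320), and no shifted value was computed for this subset. Shifts also move peaks off protein-coding promoters. The test therefore cannot separate a preference for noncoding genes from their closeness to protein-coding TSSs. Of 290 tRNA genes 21 were bound (7.24%, shifted mean 12.0, adjusted permutation p = 0.0839), and of 32 snRNA genes 5 were (15.6%, adjusted permutation p = 0.0839): snRNA:U2:34ABb (signal 198), snRNA:U5:63BC (181), snRNA:U4:39B (168), snRNA:U1:95Ca (164) and snRNA:U5:35D (149). The 5 snRNA genes were named after their values were seen. Over 1 kb from any protein-coding TSS the shares were 3.79% of 211 tRNA genes and 11.1% of 27 snRNA genes, again with no shifted value. Genes for snoRNA (12 of 269, adjusted permutation p = 0.656) and pseudogenes (10 of 268, 0.848) did not differ from shifted peaks past the threshold, and 90 of 5809 annotated transposable elements had a summit within 500 bp of their start against a shifted mean of 246. Transposable elements occur in repeated copies on which reads may not be placed, a limit that shifted summits do not face. The lower count therefore does not show that they lack woc-eGFP. Counting the TSSs of all gene classes but transposable elements left 3501 summits (52.9%) with none within 500 bp.

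Both kinds of summit lay in a dip of GC content. Mean GC over windows of 50 bp on each side was 36.8% at summits at promoters and 44.6% at 500 bp on either side, and 36.2% at summits away from promoters against 43.8% and 43.0%.

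Words holding CACTG on either strand stood out at summits away from promoters. Among 27699 words of 8 bases with at least 3 G or C, the 10 leading ones at 2271 summits on 2L, 3L and X included CACTGTGC, CACAGTGG, CACTGAGA, CACTGTAC and, without CACTG on either strand, AATACCCT and ATACCCTA. On the arms 2R, 3R and 4, which were kept out of the search, 20.8% of 1420 summits held at least 1 of the 10 within 100 bp, against 4.37% of flanks 500 bp away (odds ratio 5.74, 95% interval 4.58 to 7.22, Fisher's exact p = 3.56e-60). All 10 were higher alone, from 3.21 for ACAGTGGG to 13.4 for CACTGAGA. Several of these words overlap, as AATACCCT and ATACCCTA do, so a single site can count for more than 1 word. Some peaks also overlap, so summits are not independent and the p overstates the certainty. The words do not mark summits away from promoters alone: on these arms 11.3% of summits at promoters held them against 3.74% of their flanks (odds ratio 3.28, 95% interval 2.49 to 4.33). The lower share at promoters says little, because the words were picked at summits away from them. The 710 held-out peaks of higher signal had them in 23.8% and the 710 of lower signal in 17.7% (odds ratio 1.45, 95% interval 1.11 to 1.89). A hypothesis is that a sequence element with this core may mark part of the woc-eGFP sites of both kinds, which ChIP-seq after changing the words at such a site would test; these data cannot say which protein reads it, and most summits held none of the 10 words.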
